A study of Mus musculus with 23 samples.

How the data were processed

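Gene expression was measured on 23 Mouse Gene 1.0 ST arrays, each hybridised with RNA from 1 sorted dendritic cell population of mouse spleen. Conventional dendritic cells of type 1 (cDC1) and type 2 (cDC2) and plasmacytoid dendritic cells (pDC) came from wild-type (WT) mice and from mice with a conditional deletion of Bcl6 (cKO). The Cre driver was not given in the sources used here. There were 3 WT arrays for each cell type, 4 cKO arrays for cDC1 and 5 cKO arrays each for cDC2 and pDC. Per the labels' protocols, spleens were digested with collagenase B and DNase I, red cells were lysed, total RNA was extracted on columns and biotinylated cDNA was made with the Affymetrix WT Pico reagent kit.

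The deposited intensity values are 1 gene-level value per probe set and array. Per the submitters' processing notes they came from Affymetrix Expression Console with RMA (background correction, normalization and summarization across probes); versions were not given in the sources used here. RMA returns log2 values, but the deposited intensities run from 3.785 to 13980.744 on a linear scale, so log2 was taken before any other step. No value was centred on a gene. Array medians ranged from 29.3 to 41.2 intensity units, so the arrays do not share 1 distribution. They fell into 3 processing sets, found after the data were examined from the array medians and from which arrays deviated together from their group means. Set A held 8 arrays with medians of 29.3 to 31.0, set B 6 arrays with 31.6 to 34.3 and set C 9 arrays with 38.9 to 41.2. Each set held arrays of all 6 groups. Counts are therefore given also with the set as a fixed term, and differences also within each set. No label names these sets. Exactly equal probe set values were as frequent between sets A and B as within A. The cKO cDC1 arrays 1 (set A) and 2 (set B) shared 368 and pairs within set A up to 385, but cKO cDC1 arrays 1 and 3 (set C) only 1. The parting of A from B may therefore not mark separate processing. Sets A and B were parted by the deviations of the same genes, so a set term makes the residual smaller by construction. Its higher counts, kept calls and smaller p-values are no independent support. Scan date and slide were not given in the sources used here.

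Of 28853 probe sets, 23410 were in the table pairing probe sets with genes, 21789 with 1 gene and 1621 with several, while 5443 were unnamed there. Of the 1-gene probe sets, 21698 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier. That table was used for names and for which genes neighbour each other, and no coordinates are given. Probe sets naming several genes or none were tested apart. A probe set was kept when it exceeded the array median on at least 3 arrays, and the probe set with the highest mean stood for its gene where several passed (696 genes). This left 12157 genes of 19938.

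Tests used limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading and matplotlib 3.10.9 with numpy 2.4.6 for figures. A model of 6 group means was fitted to all 23 arrays, leaving 17 residual degrees of freedom, with lmFit and eBayes. The contrasts were cKO minus WT within each cell type, the 3 differences between those genotype effects, and the 3 pairs of cell types within each genotype. All tests were two-sided, with Benjamini-Hochberg adjustment over the 12157 genes of a contrast and a call at an adjusted p below 0.05. Errors of a log2 difference are limma standard errors (SE), and group levels are means with the standard deviation (SD). The labels do not say that arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

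The rule for named genes, the 29 gene lists, the tests and most alternatives were fixed before the data were examined. Named genes are the 10 largest rises and 10 largest falls among called genes whose cKO arrays all lay on 1 side of the WT arrays, or the 5 smallest p values as values only where fewer than 5 passed. Added to these are Bcl6, up to 4 called members of each list, up to 2 members with the largest difference of lists with none called, the 5 largest called differences between genotype effects, and up to 4 members of each identity list in WT. The lists covered cDC1, cDC2 and pDC identity, Notch2-dependent and ESAM-low cDC2 genes, dendritic cell transcription factors and BCL6-repressed genes described in B and T cells. They also covered interferon-stimulated genes, cell cycle, MHC class I and class II presentation, CCR7-type maturation, Toll-like receptors, chemokine receptors, cytokines and chemokines, C-type lectins and Fc receptors, the BCL2 family, oxidative phosphorylation, glycolysis, cholesterol synthesis, and immediate-early and heat shock genes. Markers of B, plasma, T and NK cells, red pulp macrophages, monocytes and neutrophils, erythroid cells and platelets, and sex-linked genes completed them. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry, adjusted over the 29 lists of a contrast. Intervals of list medians are 95% bootstrap intervals from 10000 resamples of the members.

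Replicate numbers come from the sample titles. Arrays of the same number deviated together from their group means in every pair for cKO against WT cDC1 (correlations 0.44 to 0.54 over 3 pairs) and for the WT pairs of cell types (0.48 to 0.65 for cDC1 and cDC2, 0.46 to 0.70 for cDC1 and pDC, 0.38 to 0.60 for cDC2 and pDC). The numbers were taken as pairing the arrays in these contrasts alone. There, however, arrays numbered 1, 2 and 3 fell in sets A, B and C, so number and processing set cannot be told apart. Where they parted, arrays 2 and 3 of cKO and WT did not deviate together (−0.08 and −0.03 in cDC2, −0.26 and −0.04 in pDC). A replicate block in these contrasts may thus stand for the set and is no separate structure. No 2 arrays were copies of each other: correlations over all probe sets ran from 0.910 to 0.995.

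The pipeline was tested on simulated data with the means and spread of the 12157 genes, of which 100 were changed by 1 and 100 by 2 log2 units. In the cDC1 contrast 42% of the smaller and 92% of the larger changes were called, with 7 false calls. The figures were 40%, 89% and 7 for cDC2, and 40%, 93% and 10 for pDC. The changed list was called in each, and no unchanged list was. The simulated spread was drawn separately for each gene, without processing sets or correlation between genes, and the simulated lists were random. These figures therefore do not give the rate of false gene or list calls on the real arrays.

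Alternatives changed 1 choice at a time: the filter (none or stricter), quantile normalization or median centring, the mean of a gene's probe sets, several-gene probe sets kept, the fit on the groups of the contrast alone, trend and robust eBayes, array weights, fixed and random replicate blocks, the Y-linked level as a covariate, B cell or macrophage marker levels as covariates, the thresholds, correlations over called or brighter genes alone, and each array left out in turn. Chosen after seeing the data were the processing set as a term, alone, with the Y-linked level, or without cKO pDC array 4; the 3 arrays with high Xist left out; and replicate blocks within the cDC1 or the WT arrays. The cKO pDC array 4 fell in set C by its median. It correlated at 0.978 to 0.980 with the pDC arrays of set A, against 0.973 and 0.975 with the other pDC arrays of set C. No alternative was left unrun. Regroupings of the arrays were tried without regard to the processing sets and, chosen after seeing the data, within them, with each set keeping its number of arrays per group.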

Results

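The study compared 3 kinds of splenic dendritic cell between wild-type mice and mice with a conditional deletion of Bcl6, which encodes a transcriptional repressor best known from germinal centre B cells and follicular helper T cells. The cDC1 present antigen to CD8 T cells, cDC2 mainly to CD4 T cells, and pDC are the main producers of type I interferon. Each of the 23 arrays held 1 sorted population. Array medians lay between 29.3 and 41.2 intensity units and followed 3 processing sets, each with WT and cKO arrays of every cell type. Cell type accounted for 52.9% of the variance between arrays, the 6 groups for 59.9%, and the 6 groups with the processing set for 86.0%. The first principal component (38.4%) parted pDC from both conventional types. WT array 1 of each cell type had high Xist (log2 levels of 10.9 in cDC1, 11.3 in cDC2 and 11.9 in pDC), the transcript of the inactive X chromosome in females, while every other array read 5.07 or less, all cKO arrays included.

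**Figure D1:**
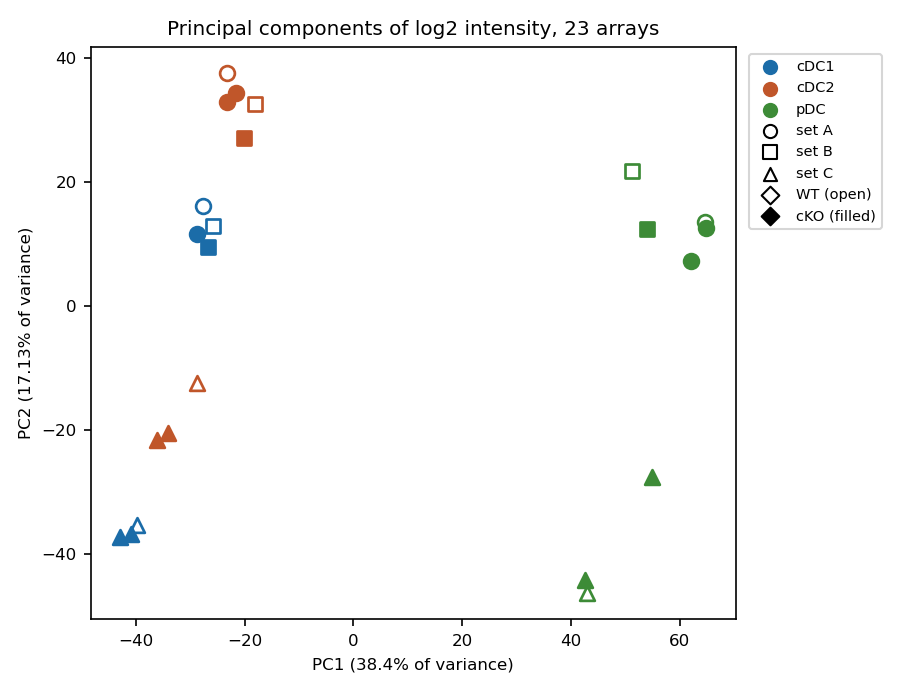
First against second principal component of log2 intensity for the 23 arrays (percent of variance on each axis); colour gives the cell type, open and filled marks WT and cKO, and the mark's shape the processing set. The pDC arrays lie apart along the first component (38.4%), and within each cell type the arrays of set C lie apart along the second (17.1%).

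The targeted gene was read by 1 probe set, which may lie outside the deleted part and then checks nothing about the deletion, so directions rest on the labels. Bcl6 read 7.42 ± 0.61 in WT cDC1 (log2, mean ± SD, n = 3) and 8.39 ± 0.29 in cKO cDC1 (n = 4), a difference of 0.97 ± 0.35 (SE; limma adjusted p = 0.598). In cDC2 the difference was 0.69 ± 0.33 (adjusted p = 0.756) and in pDC −0.15 ± 0.33 (adjusted p = 1). The cDC1 difference exceeded the SD of both groups, with an unadjusted p of 0.0108 in limma, and did not pass over all genes. The unadjusted p was 0.0483 in cDC2 and 0.659 in pDC. Within sets A, B and C the cDC1 difference was 0.62, 0.93 and 1.35. It passed in 1 alternative, the fit with the set as a term and without cKO pDC array 4, at 0.99 (adjusted p = 0.00879). The set term makes the error smaller there by construction, so this is no independent support.

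The WT arrays first showed how far the 3 populations stood apart. Against cDC2, WT cDC1 were higher in the chemokine receptor Xcr1 (36.4-fold, log2 5.19 ± 0.25, SE), the scavenger receptor Cd36 (32.6-fold), Ifi205 (20.8-fold) and the double-stranded RNA sensor Tlr3 (19.9-fold). They were lower in the lectin Cd209a (log2 −4.92 ± 0.28), the inhibitory receptor Sirpa (−4.43 ± 0.43), Clec4a4 (−4.42 ± 0.31), S100a4 (−4.30 ± 0.42) and the single-stranded RNA sensor Tlr7 (−5.17 ± 0.36). Against pDC, WT cDC1 were higher in Naaa (46.1-fold) and Xcr1 (43.9-fold) and lower in the pDC receptor Siglech (−6.94 ± 0.27), Ly6d (−7.37 ± 0.42) and the transcription factor Spib (−5.78 ± 0.45). The cDC2 exceeded pDC in Clec4a4 (21.2-fold), S100a4 (12.1-fold) and the integrin Itgam (8.42-fold) and were below them in the gut-homing receptor Ccr9 (−6.18 ± 0.40) and in Irf8 (−3.36 ± 0.42), a factor that cDC1 and pDC share. All these passed limma's test, with adjusted p of 3.28e-06 or less, and stayed called when any 1 array was left out. The lower level of 6, 7 and 4 of 12 named genes in the 3 comparisons lay below the mean of its arrays' medians, Xcr1, Tlr7, Clec4a4, Spib and Ccr9 among them, so the size of these folds is uncertain.

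In WT, 367 genes were higher and 369 lower in cDC1 than in cDC2, 1018 higher and 625 lower in cDC1 than in pDC, and 964 higher and 584 lower in cDC2 than in pDC. The balance moved with single arrays. For cDC1 against cDC2 it was 239 higher and 344 lower without WT cDC1 array 3, and 354 and 262 without WT cDC1 array 2. Without WT pDC array 2 it was 758 and 758 for cDC1 and 736 and 713 for cDC2 against pDC, and without WT pDC array 3 it was 1190 and 494, and 1100 and 435. With the replicate number as a block within the WT arrays the totals were 1459, 3034 and 2869 genes, against 736, 1643 and 1548. With the processing set as a term they were 1889, 3604 and 3539, all calls of the unblocked fit kept. Without the 3 high-Xist arrays they were 430, 1064 and 890. Of the genes higher in cDC1 than in cDC2, 367 of 367 were higher within each of the 3 sets, and 369 of the 369 lower ones were lower in each. They were called on these same arrays, so this is no separate test. The cKO arrays gave 486 higher and 602 lower genes for cDC1 against cDC2 (44.7% higher), 1525 and 960 for cDC1 against pDC, and 1642 and 884 for cDC2 against pDC. The side with more genes turned for cDC1 against cDC2 with the replicate block (1140 higher, 770 lower), array weights (1190 and 965), the random block (1024 and 933) and without cKO cDC1 array 2 (486 and 456). With the set as a term the totals were 2454, 4656 and 4768. Quantile normalization moved the share of higher genes to 54.9% and 55.2% for WT cDC1 and WT cDC2 against pDC, from 61.4% to 51.4% for cKO cDC1 against pDC and from 65.0% to 53.7% for cKO cDC2 against pDC.

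Between cKO and WT cDC1 the called differences were almost all rises: 99 genes were higher and 2 lower in cKO. Ccl24, a chemokine that attracts eosinophils, rose 87.3-fold (log2 6.45 ± 0.24, SE, n = 4 cKO against 3 WT; adjusted p = 2.85e-14), from 4.81 ± 0.27 (SD) to 11.26 ± 0.33. The inhibitory receptor Pilra rose 78.3-fold (6.29 ± 0.41) and its activating partner Pilrb1 31.0-fold (4.95 ± 0.34). The actin-capping protein Capg rose 32.9-fold (5.04 ± 0.39), the DC-SIGN-related lectin Cd209d 31.4-fold (4.97 ± 0.37) and the sialic acid receptor Cd33 25.6-fold (4.68 ± 0.27). S100a10, a partner of annexin, rose 18.9-fold, Cybb, the catalytic subunit of the phagocyte NADPH oxidase, 18.4-fold, while the lectin-like receptor Klrb1b (3.46 ± 0.24) and the phospholipid transfer protein Pltp (3.32 ± 0.40) rose by somewhat less. Their adjusted p values were 1.22e-05 or less. The 2 genes that fell were Dusp4, a phosphatase of MAP kinases (−1.22 ± 0.27, adjusted p = 0.0249), and the integrin subunit Itga3 (−0.97 ± 0.21, adjusted p = 0.0181). Scin (−0.85 ± 0.21, adjusted p = 0.0501), Rgs9 (−0.80 ± 0.19, adjusted p = 0.0544) and the inhibitory Fc receptor Fcgr2b (−1.08 ± 0.28, adjusted p = 0.0754) had the next smallest p among lower genes and did not pass. The means of Ccl24, Pilra, Capg, Cd209d, Pilrb1 and Cd33 on the WT cDC1 arrays (4.10 to 4.90) lay below the mean of those arrays' medians (5.07), as did those of 13 of the 31 named genes called. Such levels cannot be told from background, so these folds have an uncertain size and order. With the replicate block within the cDC1 arrays Fcgr2b passed, at −1.08 (adjusted p = 0.0156).

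**Figure D2:**
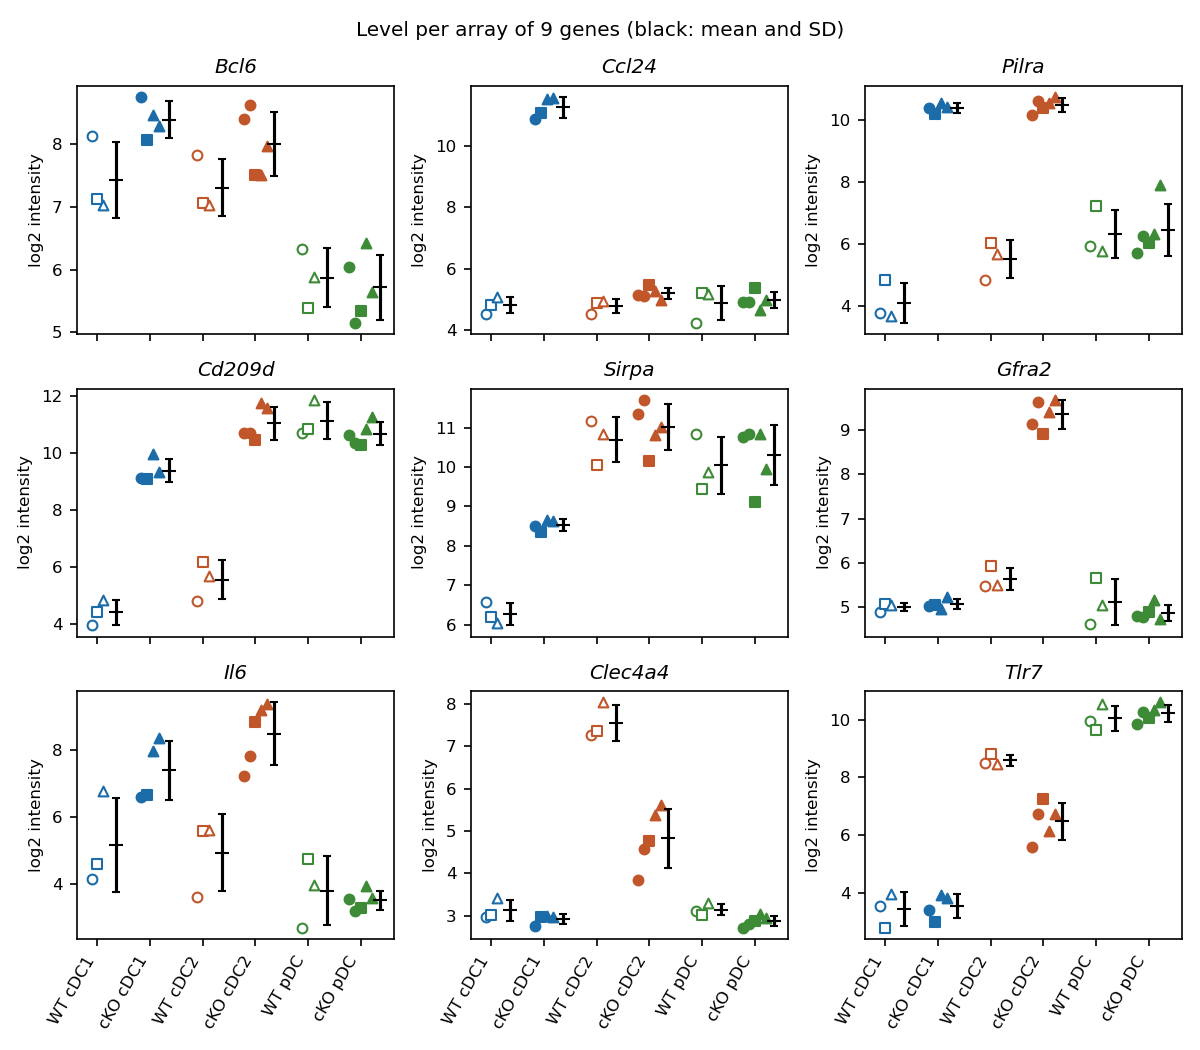
Log2 intensity of 9 genes on each array by group (open marks WT, filled marks cKO; circle, square and triangle are sets A, B and C), with the mean and SD in black. Ccl24 was high in cKO cDC1 alone, Gfra2 in cKO cDC2 alone, and Pilra in cKO arrays of both conventional types, Cd209d in these and in pDC of both genotypes, while Bcl6 was not called in any cell type.

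Of the 22 tested genes of cDC2 identity, 5 rose in cKO cDC1 and 17 did not pass. Cd209a rose 9.22-fold (3.20 ± 0.26), the transcription factor Zeb2 3.78-fold (1.92 ± 0.22), Itgam 4.42-fold (2.14 ± 0.28) and Sirpa 4.82-fold (2.27 ± 0.41). Clec4a2 was the fifth (1.72 ± 0.34), and adjusted over the list alone 7 rose. Sirpa reached 8.53 in cKO cDC1, against 10.69 in WT cDC2. The list's median (−0.01) and mean (0.58) differed in sign, since 12 members lay at or below 0. Camera called it higher (adjusted p = 5.2e-08), and with an estimated correlation it did not pass (adjusted p = 0.0996 with an estimated correlation). None of the 22 tested genes of cDC1 identity passed (median 0.08; 1 rose when adjusted over the list alone). Its largest differences were Tlr12 at 2.01-fold (adjusted p = 0.123) and Cd8a at −0.65 ± 0.26 in log2 (adjusted p = 0.822).

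The interferon-stimulated list shifted upward in cKO cDC1. Of its 27 tested members 26 lay above 0, with a median of 0.91, 6 rose over all genes tested and 16 rose when adjusted over the list alone. Ifi27l2a rose 7.10-fold (2.83 ± 0.33), the guanylate-binding Gbp3 4.41-fold (2.14 ± 0.37), the nucleic acid sensor Zbp1 2.62-fold (1.39 ± 0.29) and the RNA helicase Ddx58 2.88-fold (1.53 ± 0.35). The list was called by camera (adjusted p = 9.44e-32) and with an estimated correlation (adjusted p = 0.00632 with an estimated correlation). With the replicate block within the cDC1 arrays it did not pass camera with an estimated correlation (adjusted p = 0.175). Its median was 1.10, 0.75 and 0.76 within sets A, B and C.

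Among the 26 C-type lectins and Fc receptors 4 rose in cKO cDC1, namely Cd209d, Cd209a, Clec4a2 and Clec4n (Dectin-type receptor, 1.69 ± 0.38), and 7 rose and 1 fell when adjusted over the list alone. The list was called higher (median 0.15; adjusted p = 2.16e-05, and adjusted p = 0.845 with an estimated correlation). BCL6-repressed genes described in B and T cells were called higher too (29 tested, median 0.17; adjusted p = 0.0136, and adjusted p = 0.964 with an estimated correlation). Its 2 members that rose, also 2 when adjusted over the list alone, were the cytokine-signalling inhibitor Socs2 (3.22-fold) and the cyclin Ccnd2 (2.48-fold). That list did not pass with the stricter filter (adjusted p = 0.0908), array weights (0.0827) or the Y-linked level as a covariate (0.094). With the replicate block within the cDC1 arrays it did not pass either (adjusted p = 0.0924), nor did Ccnd2 (adjusted p = 0.0762) or Clec4n (adjusted p = 0.0844). In the same fit oxidative phosphorylation was called higher and immediate-early genes lower (adjusted p = 0.00533 for each, and adjusted p of 0.912 and 0.795 with an estimated correlation, with which the interferon-stimulated list did not pass in that fit either, at 0.175). The B cell survival factor Tnfsf13b (1.46, adjusted p = 0.0152) and Il6 (1.90, adjusted p = 0.0255) passed there. The medians within sets A, B and C were 0.07, 0.12 and 0.17 for the lectins, 0.10, 0.20 and 0.08 for the BCL6-repressed genes and −0.04, 0.12 and 0.17 for cDC2 identity.

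Single members of lists that were not called as a whole also rose in cKO cDC1: the semaphorin receptor Nrp2 of the Notch2-dependent list (8.58-fold), the CSF receptor Csf1r of the ESAM-low list (2.52-fold), Lair1 of the pDC list (2.35-fold), the chemokine receptors Ccr1 (9.44-fold) and Gpr183 (2.23-fold), the B cell inhibitory receptor Cd22 (4.67-fold) and the macrophage marker Adgre1 (2.41-fold). List medians were −0.05 for Notch2-dependent genes, −0.09 for ESAM-low genes, 0.04 for pDC identity, 0.02 for transcription factors, 0.09 for chemokine receptors, 0.08 for MHC class I and 0.14 for maturation genes. They were 0.00 for MHC class II, 0.05 for cell cycle, 0.21 for Toll-like receptors, 0.13 for cytokines and chemokines, 0.04 for the BCL2 family, 0.24 for oxidative phosphorylation, 0.05 for glycolysis, 0.05 for cholesterol synthesis and −0.21 for immediate-early and heat shock genes. Markers of other lineages had medians of −0.01 (B cells), 0.17 (plasma cells), 0.09 (T cells), 0.24 (NK cells), 0.07 (red pulp macrophages), 0.59 (monocytes and neutrophils) and 0.22 (erythroid cells and platelets), and the sex-linked list 0.83. None of these lists passed (adjusted p of 0.0834 or more). In cell cycle, glycolysis and cholesterol synthesis median and mean were above 0 while the test, which compares a list with the other genes, pointed down. The median and mean differed in sign also for Notch2-dependent, ESAM-low and B cell genes.

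With the processing set as a term 183 genes rose and 29 fell in cKO cDC1, all 101 calls kept. With the replicate block within the cDC1 arrays 138 rose and 10 fell, 90 of the 101 kept. Within each of the 3 sets, all 99 higher and both lower genes lay on their side, with a median size of 1.90, 1.82 and 1.79 log2 units in sets A, B and C. All 101 called genes had no overlap between cKO and WT arrays, which fixes their side within each set. Of the 12157 genes 4.22% had none, where chance would give 5.71% for exchangeable arrays, with the processing sets ignored. Of 31 named genes called, 21 stayed called whichever 1 array was left out; Adgre1, Ccnd2, Clec4a2, Clec4n, Csf1r, Ddx58, Dusp4, Gpr183, Itga3 and Zbp1 did not (adjusted p of 0.0506 to 0.283 where the call ended). The total fell to 66 without WT cDC1 array 2, and to 68 (67 of the 101 kept) without the 3 high-Xist arrays. With the random replicate block Dusp4, Ddx58 and Adgre1 did not pass limma's test (adjusted p of 0.0584, 0.0804 and 0.0561).

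In cDC2, 141 genes were higher and 49 lower in cKO than in WT. Cd209d rose 45.0-fold (5.49 ± 0.36, SE, n = 5 cKO against 3 WT; adjusted p = 1.22e-09), Pilra 31.5-fold (4.98 ± 0.40), Capg 23.5-fold (4.55 ± 0.37) and Pilrb1 12.1-fold (3.59 ± 0.32). Gfra2, a receptor subunit for the neurotrophic factor neurturin, rose 13.1-fold (3.71 ± 0.22), from 5.64 in WT to 9.35 in cKO. The fungal receptor Clec4n rose by 3.71 ± 0.36, the inflammatory cytokine Il6 11.7-fold (3.54 ± 0.61, adjusted p = 0.00141), the chemokine receptor Ccr1 10.8-fold, fibronectin (Fn1) 8.29-fold and the interleukin receptor Il1rl2 8.18-fold. The largest fall was in Clec4a4, an inhibitory lectin that marks splenic cDC2, by 6.59-fold (−2.72 ± 0.28, adjusted p = 1.96e-06). The secreted nuclease Dnase1l3 (−2.23 ± 0.35), the ion cotransporter Slc12a2 (−2.22 ± 0.29), Cd300ld (−2.18 ± 0.29), Tlr7 (−2.11 ± 0.32) and the efflux pump Abcb1a (−1.83 ± 0.25) fell as well. Also lower were Ppp1r14a (−1.86 ± 0.44), the ubiquitin-conjugating enzyme Ube2e2 (−1.78 ± 0.29), the metabolic coactivator Ppargc1a (−1.67 ± 0.37) and the adhesion molecule Dscam (−1.65 ± 0.24), with adjusted p of 0.0286 or less. The WT means of Il6 (4.94), Ccr1 (4.26) and Il1rl2 (4.23) lay below the mean of those arrays' medians (5.06), as did the cKO means of Clec4a4 (4.83) and Ppargc1a (4.21, against 5.11). The lower level was below it in 9 of the 48 named genes called, and the size and order of such folds is uncertain.

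The cDC2 identity list divided: 4 of 22 rose, among them the galactose-type lectins Clec10a (5.31-fold) and Mgl2 (4.01-fold), and 3 fell, among them Clec4a4 and the Notch pathway gene Dtx1 (−1.62 ± 0.17). Adjusted over the list alone 5 rose and 3 fell, and the list as a whole was not called (median 0.17; adjusted p = 0.984). Of the 14 Notch2-dependent genes Nrp2 rose (3.75-fold) and Clec4a4 and Dtx1 fell (2 higher and 2 lower over the list alone; median −0.03; adjusted p = 0.0625). Of the 14 ESAM-low, monocyte-like genes 4 rose and 2 fell (5 and 2 over the list alone; median 0.73; adjusted p = 0.231). Ccr2, the receptor that draws monocytes to tissue, rose 3.84-fold and Csf1r 2.79-fold, while the lectin Clec12a (−1.16 ± 0.22) and the granulocyte receptor Csf3r (−1.29 ± 0.25) fell. The cDC1 identity list was called higher (22 tested, median 0.35; adjusted p = 0.000468, and adjusted p = 0.431 with an estimated correlation), with 3 members that rose, 4 over the list alone: Cd36 (2.95-fold), Naaa (2.15-fold) and the endosomal Rab7b (1.90-fold).

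Cytokines and chemokines rose as a list in cKO cDC2, with 5 of 31 members called, 9 over the list alone, and a median of 0.60 (adjusted p = 2.03e-07, and adjusted p = 0.353 with an estimated correlation). Besides Il6, Ccl22, which attracts regulatory T cells, rose 4.39-fold, Il12b, a subunit shared by cytokines that direct T cells, 3.97-fold and Tnfsf4, a co-stimulatory ligand for T cells, 3.27-fold. Chemokine receptors were called higher (4 of 19, 7 over the list alone, median 0.06; adjusted p = 0.000104, and adjusted p = 0.306 with an estimated correlation), with Ccr1, Ccr2, Cxcr6 (3.25-fold) and the lymphocyte egress receptor S1pr1 (2.19-fold). C-type lectins and Fc receptors were called higher with 6 members up and 2 down of 26, 9 and 3 over the list alone (median 0.48; adjusted p = 5.91e-05, and adjusted p = 0.431 with an estimated correlation). BCL6-repressed genes were called higher with 4 up and 1 down of 29, 7 and 2 over the list alone (median 0.48; adjusted p = 0.00138, and adjusted p = 0.465 with an estimated correlation). Among them were Il7r (4.01-fold), Socs2 (3.42-fold), the T cell factor Gata3 (2.58-fold) and S1pr1. The factor Tbx21 fell (−0.87 ± 0.22, adjusted p = 0.0403) and the retinoic acid receptor Rara rose (2.65-fold), the only dendritic cell transcription factors of 38 called, against 4 up and 2 down over the list alone (median 0.16; adjusted p = 0.323). Interferon-stimulated genes were all above 0 (27 of 27, median 0.65; adjusted p = 1.7e-09, and adjusted p = 0.203 with an estimated correlation), with Gbp3 (3.94-fold) the member called and 4 over the list alone.

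Markers of other lineages moved in cKO cDC2 as well. T cell markers were called higher (median 0.69, 9 of 10 above 0; adjusted p = 4.26e-06, and adjusted p = 0.203 with an estimated correlation) with Thy1 (2.21-fold) and Cd6 (1.78-fold), 6 over the list alone. NK cell markers were called higher (median 0.60, 7 of 8 above 0; adjusted p = 0.000484, and adjusted p = 0.203 with an estimated correlation) with the cytokine receptor chain Il2rb (4.22-fold), 3 over the list alone. Red pulp macrophage markers were called higher (median 0.25; adjusted p = 0.00108, and adjusted p = 0.431 with an estimated correlation) with the efferocytosis receptor Mertk (5.30-fold) and Cd163 (1.69-fold), 4 over the list alone. B cell markers were called lower (median −0.16, adjusted p = 0.00131, and adjusted p = 0.431 with an estimated correlation) with none of 15 called in limma's test, 0 over the list alone. Ms4a1 (−1.51 ± 0.49, adjusted p = 0.212) and Cd22 (−0.67 ± 0.26, adjusted p = 0.421) had the largest differences. Without the high-Xist arrays the calls of cDC1 identity, lectins, NK and macrophage markers ended (adjusted p of 0.102, 0.102, 0.0714 and 0.0714). With the stricter filter those of T cell markers, BCL6-repressed genes and macrophage markers ended (adjusted p of 0.152, 0.152 and 0.372). With the B cell level as a covariate that of NK markers did (adjusted p = 0.121).

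Of the other lists, monocyte and neutrophil markers had a median of 0.61 (Fn1 and Ccr2 rose, Csf3r fell; adjusted p = 0.08), maturation genes 0.11 (3 rose, or 7 with 2 that fell when adjusted over the list alone; adjusted p = 0.061), pDC identity 0.12 (Tlr7 and Lair1 fell) and Toll-like receptors 0.29 (Tlr7 fell). The median was 0.07 for cell cycle, 0.05 for MHC class II, 0.18 for MHC class I, 0.15 for the BCL2 family, 0.06 for oxidative phosphorylation, 0.26 for glycolysis 0.20 for cholesterol synthesis, −0.14 for immediate-early genes, −0.01 for plasma cell markers, 0.18 for erythroid and platelet markers and 0.88 for sex-linked genes, and no member was called. Mean and median differed in sign for MHC class II and Toll-like receptors, and the test pointed down for cell cycle and pDC identity although both were above 0. Medians within sets A, B and C were 0.70, 0.20 and 0.58 for cytokines, 0.76, −0.00 and 0.66 for lectins, 0.28, 0.73 and 0.78 for interferon-stimulated genes, 0.89, 0.60 and 0.41 for T cell markers and 1.20, 0.41 and 0.81 for NK markers. They were 0.55, 0.06 and 0.31 for cDC1 identity, 0.34, 0.38 and 0.37 for BCL6-repressed genes, 0.21, 0.02 and 0.43 for chemokine receptors, 0.23, 0.18 and 0.27 for macrophage markers and −0.21, −0.30 and −0.08 for B cell markers.

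With the processing set as a term, which makes the residual smaller by construction, 369 genes rose and 190 fell in cKO cDC2, all 190 calls kept. With the macrophage level as a covariate 84 rose and 92 fell, 120 of the 190 kept, and with a replicate block 147 and 121, 172 kept. Within each set 139 of the 141 higher and all 49 lower genes lay on their side, with a median size of 1.58, 1.19 and 1.40 log2 units. Of the called genes 180 had no overlap between genotypes, which fixes their side within each set. Of the 12157 genes 4.71% had none, where chance would give 3.57% for exchangeable arrays, with the processing sets ignored. Of 48 named genes called, 33 stayed called whichever 1 array was left out, and 15 did not: Cd163, Cd6, Clec10a, Clec12a, Csf3r, Gata3, Lair1, Mgl2, Naaa, Ppargc1a, Ppp1r14a, Rab7b, S1pr1, Tbx21 and Thy1 (adjusted p of 0.0502 to 0.291 where the call ended). The genes that fell numbered 28, 31 and 25 without WT cDC2 array 1, 2 or 3. The total was 107 without WT cDC2 array 1, 123 without array 2 and 106 (99 of the 190 kept) without the 3 high-Xist arrays.

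In pDC few genes passed: 4 rose and none fell, against 242 genes at an unadjusted p below 0.05. Gm12253, a predicted gene, rose 3.84-fold (1.94 ± 0.19, SE, n = 5 cKO against 3 WT; adjusted p = 5.39e-06), and 1810065E05Rik, its direct neighbour in the genome annotation, 4.25-fold (2.09 ± 0.33, adjusted p = 0.0123). Slfn5, of an interferon-inducible family, rose 3.43-fold (1.78 ± 0.31, adjusted p = 0.0307) and the interferon-stimulated Oasl2 2.49-fold (1.32 ± 0.23, adjusted p = 0.0266). Sdc3 at 1.37 ± 0.26 (adjusted p = 0.0701) did not pass, nor did the lowest p among lower genes, Xlr at −1.46 ± 0.33 (adjusted p = 0.257), Etfbkmt at −0.80, Smpdl3a at −0.78, Adgre4 at −1.02 and Zfp160 at −0.76. With the processing set as a term 20 genes rose and 6 fell, the 4 among them, and all 4 were higher within each set (median size 1.54, 2.13 and 1.61). They had no overlap between genotypes, which fixes their side within each set. Of the 12157 genes 0.666% had none, where chance would give 3.57% for exchangeable arrays, with the processing sets ignored.

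Interferon-stimulated genes rose together in cKO pDC. All 27 tested members were above 0, with a median of 0.89 and 16 called when adjusted over the list alone, although Oasl2 alone passed over all genes. The list was called by camera (adjusted p = 2.88e-33) and with an estimated correlation (adjusted p = 0.00498 with an estimated correlation), and its median was 0.90, 0.70 and 0.82 within sets A, B and C. Irf7, the factor that drives type I interferon production in pDC, read 1.53 ± 0.45 higher (adjusted p = 1).

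**Figure D3:**
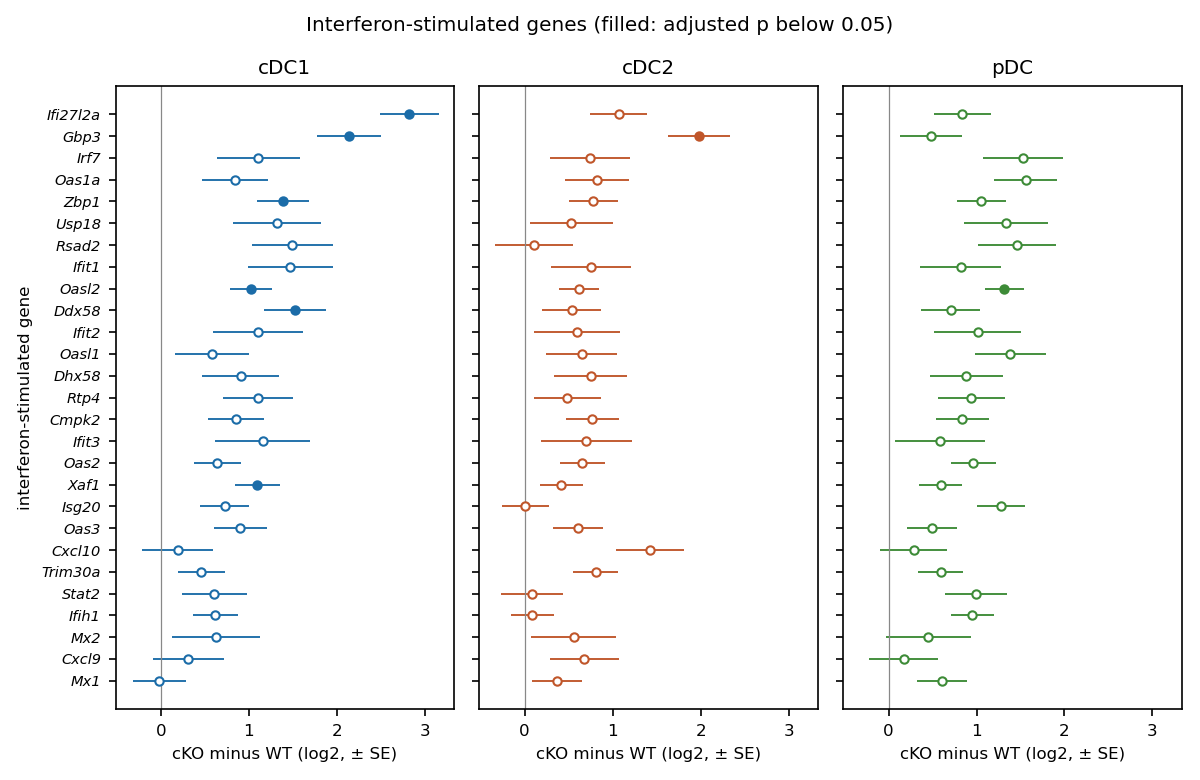
Difference between cKO and WT (log2, with SE) of the 27 tested interferon-stimulated genes in cDC1, cDC2 and pDC; filled points passed at an adjusted p below 0.05. Nearly all points lie to the right of 0, with medians of 0.91 in cDC1, 0.65 in cDC2 and 0.89 in pDC.

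Lists called lower in pDC had no member that passed, in limma's test over all genes or over the list alone. They were ESAM-low genes (median −0.20; adjusted p = 2.15e-05, and adjusted p = 0.234 with an estimated correlation), lectins and Fc receptors (−0.20; adjusted p = 4.72e-05, and adjusted p = 0.642 with an estimated correlation), maturation genes (−0.14; adjusted p = 0.00742, and adjusted p = 0.71 with an estimated correlation), red pulp macrophage markers (−0.15; adjusted p = 0.00952, and adjusted p = 0.71 with an estimated correlation) and NK markers (−0.50; adjusted p = 0.0211, and adjusted p = 0.642 with an estimated correlation). Fcgr4 (−1.24 ± 0.41) and Klre1 (−1.01 ± 0.38) showed large differences in them without passing. With the processing set as a term camera did not call NK markers (adjusted p = 0.118). Medians within sets A, B and C were −0.43, −0.43 and −0.07 for ESAM-low genes, −0.08, −0.34 and −0.06 for lectins, −0.05, −0.14 and −0.17 for maturation genes, −0.09, −0.48 and 0.04 for macrophage markers and −0.03, −1.41 and −0.11 for NK markers. Without WT pDC array 2 none of these 5 passed in its direction: the mean was 0.11 for NK and −0.05 for macrophage markers, where the test turned without passing (adjusted p of 0.315 and 0.777), and adjusted p was 0.315 for ESAM-low genes, 0.237 for maturation genes and 0.759 for lectins. The pDC identity list did not pass (median 0.10; adjusted p = 0.238), nor did cDC1 identity (−0.03), cDC2 identity (0.05), T cell markers (−0.08), B cell markers (−0.01), cytokines (−0.15), oxidative phosphorylation (−0.11) or cell cycle (0.05). In pDC the median and mean differed in sign for BCL6-repressed, B cell, and erythroid and platelet genes. They were above 0 with a test pointing down for cDC2 identity, Notch2-dependent genes, chemokine receptors, immediate-early genes and monocyte markers.

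The pDC count moved with single arrays, from 1 without WT pDC array 2 to 7 without WT pDC array 3 or cKO pDC array 3, and was 2 without WT pDC array 1 or cKO pDC arrays 2, 4 or 5. Gm12253 stayed called whichever 1 array was left out, while 1810065E05Rik (adjusted p up to 0.319), Slfn5 (up to 0.619) and Oasl2 (up to 0.525) did not; in the fit on the pDC arrays alone no gene passed, Gm12253 included (adjusted p = 0.0598).

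The genotype effects of cDC1 and cDC2 overlapped. Of the 99 genes that rose in cDC1, 40 also rose in cDC2, and 89 lay above 0 there, with a median of 0.81. Independent lists would share 1.15, but WT cDC1 and WT cDC2 arrays of the same number deviated together (0.48 to 0.65), so neither this number nor the jackknife error accounts for that. Of 216 joint splits of the cDC1 and cDC2 arrays within the processing sets the real one gave 40 genes higher in both, and none of the others gave any. Apart from the real split, however, those of cDC1 called 0 genes and those of cDC2 at most 2. The absence of shared genes thus follows from the separate counts and does not test the overlap beyond them. With the set as a term the real split gave 86, against 1 at most. The splits do not keep the replicate numbers together, and the correlation of another split reached 0.379. Cd209d, Pilra, Capg, Pilrb1, Cd33, Ccr1, Nrp2 and Klrb1b were among the 40. No gene fell in both, and 2 went opposite ways: the transglutaminase Tgm2 rose in cDC1 (1.57 ± 0.23) and fell in cDC2 (−1.59 ± 0.22), and Lair1 did the same (1.23 ± 0.22 and −1.05 ± 0.21). Across genes, which are not independent replicates, the effects correlated with r = 0.392 between cDC1 and cDC2 (Spearman 0.217; jackknife SE 0.157 over arrays), 0.0505 between cDC1 and pDC (−0.0347; SE 0.293) and 0.139 between cDC2 and pDC (0.131; SE 0.221). Gbp7 and the aminoacid exchanger subunit Slc7a11 were also in the shared set. Oasl2 alone rose in both cDC1 and pDC (0.033 expected), and no gene rose in both cDC2 and pDC (0.046 expected). These expected numbers also take the lists as independent, although WT arrays of the same number deviated together (0.46 to 0.70 and 0.38 to 0.60).

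**Figure D4:**
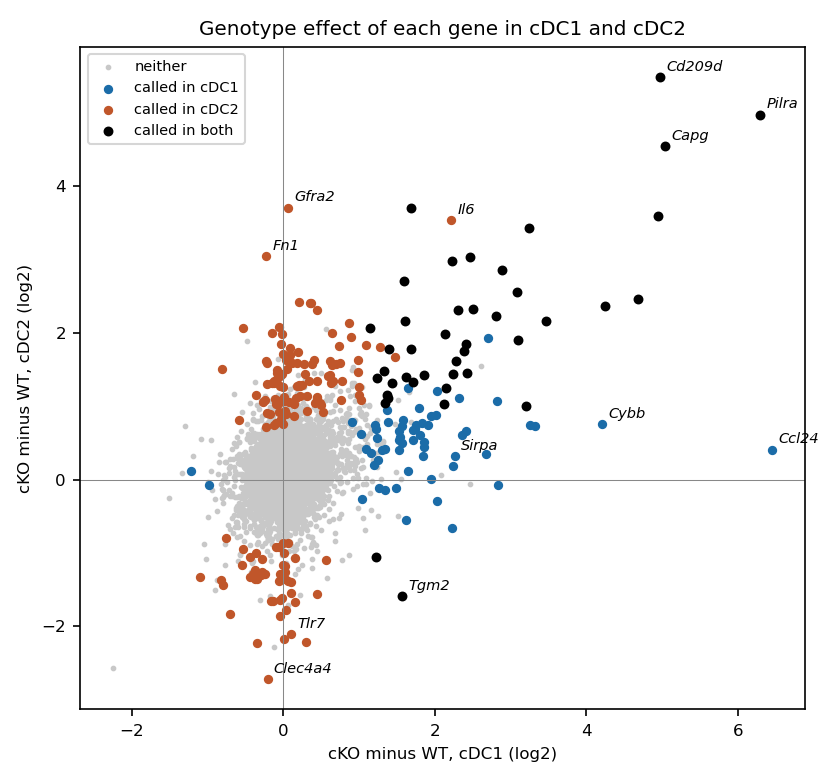
Difference between cKO and WT (log2) of each of the 12157 tested genes in cDC1 (horizontal) and cDC2 (vertical); colour marks genes called in cDC1, in cDC2, in both or in neither. Most genes called in both lie at the upper right, with Tgm2 among the exceptions and Ccl24 and Gfra2 each close to 1 axis.

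Tests of the difference between effects showed where cell types parted. The effect on Ccl24 was larger in cDC1 than in cDC2 (6.04 ± 0.34, SE; adjusted p = 1.19e-10), as was that on Cybb (3.45 ± 0.48, adjusted p = 0.000482) and Tgm2 (3.16 ± 0.32, adjusted p = 5.84e-06), while the effect on Gfra2 (−3.64 ± 0.31, adjusted p = 3.65e-07) and Fn1 (−3.27 ± 0.54, adjusted p = 0.00334) was the larger in cDC2. In all, 34 genes differed (21 and 13). The cDC1 effect exceeded the pDC effect most in Ccl24 (6.36), Pilra (6.16), Cd209d (5.43), Capg (4.30) and S100a10 (4.26), among 39 higher and 1 lower. The cDC2 effect exceeded it most in Cd209d (5.95), Pilra (4.85), Gfra2 (3.95), Il6 (3.84 ± 0.86, adjusted p = 0.0418) and Capg (3.81), among 44 higher and 15 lower. Several of these genes, Ccl24 and Pilra in WT cDC1 and Il6 in WT cDC2 among them, had a level below the array medians, so the size and order of these differences is uncertain as well. With the processing set as a term the 3 totals were 148, 95 and 218, all calls kept, and every called difference had its sign within each set. Neither is separate support, since the sets and the calls come from the same arrays. Quantile normalization moved the share of higher differences between cDC2 and pDC from 74.6% to 60.3%.

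Among lists 9 differed between cDC1 and cDC2, 9 between cDC1 and pDC and 12 between cDC2 and pDC, none of them with an estimated correlation. The effect on cDC2 identity genes was more upward in cDC1 than in cDC2 (median difference 0.33; adjusted p = 3.07e-08, and adjusted p = 0.16 with an estimated correlation). Cytokines and chemokines rose more in cDC2 than in cDC1 (median −0.37; adjusted p = 0.000494, and adjusted p = 0.67 with an estimated correlation) and than in pDC (0.52; adjusted p = 1.24e-09, and adjusted p = 0.167 with an estimated correlation). The interferon-stimulated rise was smaller in cDC2 than in cDC1 (0.41; adjusted p = 0.000462, and adjusted p = 0.67 with an estimated correlation) and than in pDC (−0.25; adjusted p = 0.00624, and adjusted p = 0.624 with an estimated correlation). Within sets A, B and C its median difference was 0.75, 0.16 and 0.11 against cDC1 and −0.46, −0.23 and −0.07 against pDC, so the gap was largest in set A, which holds the high-Xist WT arrays. Without these arrays it was 0.24 (adjusted p = 0.0142) and −0.11 (adjusted p = 0.044). The cytokine difference within the sets was −0.40, −0.06 and −0.48 against cDC1 and 0.50, 1.02 and 0.59 against pDC, and that of cDC2 identity 0.45, 0.78 and 0.41. Without the high-Xist arrays 17, 24 and 24 genes differed, and Fn1 did not pass (adjusted p = 0.067). The total for cDC1 against cDC2 was 22 without WT cDC1 array 2 or WT cDC2 array 2, that for cDC2 against pDC was 39 without WT cDC2 array 2, and Il6 lost its call without any of 13 arrays in turn (adjusted p of 0.0512 to 0.225).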

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

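Of the tests in this part, the splits within the processing sets, the tests of other lineages as the whole source and that of the ESAM-high subset as the source of ESAM-low genes that fell, and the fits with the set as a term or without the high-Xist arrays, were chosen only after the result was seen. The genotype effects differed between cell types in 34 genes for cDC1 against cDC2, 40 for cDC1 against pDC and 59 for cDC2 against pDC, by tests of the difference itself. For cDC1 against cDC2 the differences were 6.04 in Ccl24, −3.64 in Gfra2, 3.45 in Cybb, −3.27 in Fn1 and 3.16 in Tgm2, and each kept its sign within the 3 sets. For cDC1 against pDC they were 6.36 in Ccl24, 6.16 in Pilra, 5.43 in Cd209d, 4.30 in Capg and 4.26 in S100a10. For cDC2 against pDC they were 5.95 in Cd209d, 4.85 in Pilra, 3.95 in Gfra2, 3.84 in Il6 and 3.81 in Capg.

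Regroupings of the arrays set these counts against chance. In cDC1 the real split was the 1 of 35 that gave as many as 101 genes (highest other 45), and in cDC2 the 1 of 56 that gave 190 (highest other 5), but these splits ignored the processing sets. Within the sets the real split was 1 of 12 in cDC1 (highest other 0, or 64 against 212 with the set as a term), and 1 of 18 in cDC2 (highest other 2, or 33 against 559). In cDC1 8 of the 12 also part the numbered pairs. These are too few for a share under 0.05, so chance was excluded only among splits that ignore the sets. In pDC 7 of 56 splits gave 4 genes or more, so chance was not excluded there. Its highest other split gave 1006 genes and put cKO pDC arrays 1, 2 and 4 with WT arrays 1 and 3, so that both arrays of set B lay on the other side with cKO array 5, which points to a structure of the samples. Within the sets the real split was the 1 of 18 with 4 genes or more, and with the set as a term 2 of 18 gave 26 or more. For the differences between effects 2 of 100 splits gave as many for cDC1 against cDC2 (34, highest other 61) and 4 of 100 for cDC1 against pDC (40, highest other 77). Within the sets 3 of 100 did for cDC1 against cDC2 (highest other 68) and 10 of 100 for cDC1 against pDC (highest other 56). The labels were regrouped separately in each cell type, so a split can keep the real labels of 1 type. The genotype effect of that type then counts as a difference. These shares therefore cannot decide on chance, which was not excluded for either difference, and the higher counts do not by themselves show a structure of the samples. For cDC2 against pDC 5 of 100 splits gave as many (59, highest other 3401), so chance was not excluded, and the highest again points to a structure of the samples. Within the sets 3 of 100 did (highest other 64), and with the set as a term 8 of 100 gave as many as the real 218.

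Between cell types the real split was the 1 of 100 with as many genes for cKO cDC1 against cDC2 (1088, highest other 506), cKO cDC1 against pDC (2485, highest other 1328) and cKO cDC2 against pDC (2526, highest other 759). Within the sets it was the 1 of 36 in each case (highest others 506, 1166 and 0), which excluded chance only among splits that ignore the replicate numbers. The cKO cDC2 and cKO pDC arrays numbered 1, 2, 3 and 5 deviated together (0.57 to 0.62), while those numbered 4 did not (−0.05). In WT the 10 splits are too few for a share under 0.05. The real split, 1 of the 10 in each case, gave 736, 1643 and 1548 genes and the highest others 0, 1 and 1. Within the sets, which part the numbered pairs, there are 4.

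The first pattern is the 40 genes that rose in both cKO cDC1 and cKO cDC2, among them Cd209d, Pilra, Pilrb1, Capg, Cd33 and Ccr1. Of them, 100% were higher within each of the 3 sets in both cell types. All 101 genes called in cDC1 and 180 of those called in cDC2 had no overlap between genotypes, which fixes that sign. The percentage was thus largely set by the selection and cannot test the processing set as a cause. Without the high-Xist arrays the median kept at least 92.2% of its size (2.26 to 2.21 in cDC1, 1.94 to 1.79 in cDC2), with 34 and 32 still called. The kept size was likewise largely set by the selection on the same arrays and cannot test sex as a cause. The genes still called differ between genotypes among arrays of low Xist, which argues against sex as the whole cause for those genes alone. Spill of cDC2 into the cDC1 sort would need a median of 84.5% cDC2 RNA (interval 69.4 to 111), while 12 other cDC2 genes allowed 1.25% (−0.33 to 10.99). The 40 genes were chosen because they rose in cDC1, and all of them, the cDC2 gene Cd209a included, were kept out of the 12. The gap between these percentages is thus in part set by the selection. Cells of another lineage may add to the pattern, because T cell markers had a median of 0.685 in cDC2 (interval 0.27 to 1.15). In cDC1 the upper limits of the 5 lineages, on all arrays or without any 1, reached 1.569 at most. The shared genes' lower limit there was 1.742 or more. Within set C alone monocyte and neutrophil markers, at 1.321 with an interval of 0.337 to 2.817, did reach the shared genes at 1.794 to 2.529. In cDC2 the upper limits of the lineages reached 1.959 (monocytes and neutrophils), above 1.524. A fold depends on the level a gene starts from, and the shared genes were chosen because they rose. Medians of marker lists therefore cannot exclude another lineage as the whole source, which stays open in both cell types. Loss of repression by BCL6 in both types is the biological explanation that the design names, and it stays open as a hypothesis.

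The second pattern is the rise of interferon-stimulated genes in cKO pDC. The processing set is argued against, since the list's median was 0.703 or more within each set. Sex of the WT animals of array 1 is argued against as well, since the median kept 95.8% of its size without those arrays (0.85; adjusted p = 2.21e-15). The same list rose in cDC1 and cDC2. Camera with an estimated correlation did not pass in cDC2 (adjusted p = 0.203), nor in cDC1 with the replicate block within its arrays (adjusted p = 0.175). A signal reaching all 3 cell types, such as interferon in the cKO animals, may lie behind the rise as well as the loss of BCL6 in each cell, and no test here parts these. Whether the animals of either genotype were kept or sorted apart was not given in the sources used here.

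The third pattern is the 49 genes that fell in cKO cDC2, with Clec4a4, Dtx1, Dnase1l3 and Tlr7 among them, a number that was 28, 31 and 25 without WT cDC2 array 1, 2 or 3. Of them, 100% were lower within each set. Most genes called in cDC2 had no overlap between genotypes, which fixes that sign, so the percentage cannot test the processing set as a cause. Without the high-Xist arrays the median was 102.8% of its size (−1.33 to −1.37), which the selection on the same arrays largely set, so it cannot test sex as a cause. With fewer arrays 25 of the 49 stayed called. These 25 differ between genotypes among arrays of low Xist, which argues against sex as the whole cause for them alone. A smaller share of the ESAM-high subset, which carries Clec4a4, may contribute: the 12 ESAM-low genes not called lower had a median of 0.772, but with an interval of −0.36 to 1.46 this cannot be told apart from no shift. Of the 49, Clec12a and Csf3r are ESAM-low genes, which a smaller share would raise. Both fell in every fit when adjusted over the list alone (−1.16 ± 0.22 and −1.29 ± 0.25, SE), while 4 others rose. Without WT cDC2 array 3 they read −0.88 ± 0.23 and −0.90 ± 0.24, and limma's call over all genes ended (adjusted p of 0.0664 and 0.0876). On the cDC2 arrays alone the folds were the same, and a wider error (± 0.27 and ± 0.29) ended it (adjusted p of 0.078 and 0.0643). The 2 genes were already called lower on these arrays, so their fall in refits was largely fixed. A smaller share beside lower expression is not excluded for them either, so the smaller share stays open for all 49. Reduced expression within cDC2 stays open, as a hypothesis.

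Single arrays lay far from the rest of their group in 3 of 135 groups of values tested, where chance gives about 1 in 20. That is no more than chance would give. Pilrb1 read 9.52 on cKO cDC1 array 2, against 9.83 to 9.88 on the others of its group. NK cell markers averaged 6.03 on cKO cDC1 array 4, against 5.83 to 5.85, and cholesterol synthesis genes 7.001 on cKO pDC array 3, against 7.63 to 7.85. Among 3250 probe sets that name several genes or none, which the genes tested did not include, 13 were higher in cKO cDC1, 14 in cKO cDC2 and 2 in cKO pDC, of which 6, 5 and 2 name several genes. In cKO cDC2 1 was lower, and none in cDC1 or pDC.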

How the results depend on the processing

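The fits with the processing set as a term, those without the high-Xist arrays and those with a replicate block within the cDC1 or WT arrays were chosen only after the results were seen. The sets were drawn in part from deviations of the same genes, so counts with the set as a term can be too high. Of 134 calls of named genes, 134 were kept with the set as a term, 113 on the groups of the contrast alone and 110 without the high-Xist arrays, and none reversed in any alternative. The interferon-stimulated list was higher and called in all 42 alternatives in cDC1 (mean 0.87 to 1.17), all 41 in cDC2 (0.37 to 0.82) and all 41 in pDC (0.71 to 1.05), apart from the estimated correlation. In the other alternatives that kept all arrays or dropped several, 92 results of named genes gained and 95 lost a call, as did 59 and 30 of lists. Except where fewer arrays, a lower threshold or another set test explains a change by its construction, the cause was not tested. Arrays give no depth, and the filter asked for a level above the array median on 3 of 23 arrays only, so that a group of a tested gene may lie at background.

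With the processing set as a term the counts were 212 in cDC1, 559 in cDC2 and 26 in pDC, 148, 95 and 218 for the differences between effects (cDC1 against cDC2, cDC1 against pDC, cDC2 against pDC, the order used from here on), 1889, 3604 and 3539 between WT cell types and 2454, 4656 and 4768 between cKO cell types. With the Y-linked level added they were 196, 451 and 28, then 152, 114 and 222, 1903, 3599 and 3559, and 2445, 4572 and 4755. With the set and without cKO pDC array 4 they were 243, 655 and 19, then 181, 97 and 208, 2144, 3985 and 3920, and 2751, 4501 and 4768, and Bcl6 was higher in cKO cDC1 by 0.99 (adjusted p = 0.00879).

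A replicate block gave 69 and 78 genes for the differences of cDC1 against cDC2 and pDC, 1158 for WT cDC1 against cDC2, and 1910 and 3878 for cKO cDC1 against cDC2 and pDC. A random block gave 109, 83 and 150 for the differences, 1377, 2748 and 2633 in WT, and 1957 and 4074 for cKO cDC1 against cDC2 and pDC. The block within the WT arrays gave 1459, 3034 and 2869. Array weights gave 271 genes in cDC1, 1 in pDC, 72 for the difference of cDC1 against cDC2, and 2155, 6303 and 4200 between cKO cell types. The iteration that estimates these weights stopped before it reached its tolerance, so the counts with array weights are less certain than the others.

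Without the high-Xist arrays 106 genes were called in cDC2, 17, 24 and 24 for the differences and 430, 1064 and 890 in WT, and 10 lists were called in cDC1. On the groups of the contrast alone, WT cDC1 and cDC2 against pDC gave 1002 and 937 genes and the pDC genotype contrast 0 in limma's test, against 242 genes at an unadjusted p under 0.05 in the fit to all arrays. The B cell level as a covariate gave 475 genes in cDC2 and 7 in pDC, the macrophage level 7 in pDC and quantile normalization 7 in pDC. With the Y-linked level as a covariate the correlation of the cDC2 and pDC effects was 0.394.

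At an adjusted p below 0.01, 108 genes were called in cDC2, 1 in pDC, 20 for the difference of cDC1 against cDC2, 33 for cDC2 against pDC, 487 and 1008 for WT cDC1 against cDC2 and WT cDC2 against pDC, and 707 for cKO cDC1 against cDC2. At 2-fold or more, cKO cDC1 and cDC2 against pDC gave 1595 and 1549. With an estimated correlation 1, 0 and 1 lists were called in cDC1, cDC2 and pDC, and with fry 2, 4 and 1.

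With each array left out in turn, cDC1 gave 66 to 108 genes (66 without WT cDC1 array 2), cDC2 107 to 209 (107 without WT cDC2 array 1, 123 without array 2) and pDC 1 to 7 (1 without WT pDC array 2, 7 without WT or cKO pDC array 3, 2 without WT pDC array 1 or cKO pDC arrays 2, 4 or 5). The difference of cDC1 against cDC2 gave 22 to 37 (22 without WT cDC1 or WT cDC2 array 2) and that of cDC2 against pDC 39 to 66 (39 without WT cDC2 array 2). Lists called were 3 to 10 in cDC1 (10 without WT cDC1 array 1, 8 without array 2) and 5 to 11 in pDC (11 without cKO pDC array 3). In pDC the mean of NK markers ran from −0.70 to 0.11 and that of macrophage markers from −0.20 to −0.053, and both turned in test direction without WT pDC array 2, at 0.11 and −0.053.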

Other observations

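Further genes among the 40 that rose in both conventional types are given here as single values, without a test of any class. Pilrb2, a relative of Pilrb1, rose in cDC1 (2.31 ± 0.33, SE) and cDC2 (2.32 ± 0.32), the nucleotide receptor P2ry13 by 2.81 ± 0.27 and 2.24 ± 0.26, and the leukotriene receptor Cysltr1 by 2.22 ± 0.33 and 2.98 ± 0.32. The lipid-presenting molecule Cd1d1 rose by 1.15 ± 0.27 and 2.07 ± 0.25, the growth factor Hbegf by 2.38 ± 0.40 and 1.76 ± 0.38, and the sialomucin Cd164 by 2.28 ± 0.18 and 1.62 ± 0.17. Among enzymes, Upb1, which acts in pyrimidine breakdown, rose by 3.08 ± 0.22 and 2.56 ± 0.21, Lpcat2, which makes platelet-activating factor, by 2.43 ± 0.27 and 1.46 ± 0.26, and the adenylate kinase Ak8 by 2.89 ± 0.48 and 2.86 ± 0.45. These genes were chosen after their values were seen, and none was called in pDC.

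The places of a few pairs of called genes in the annotation were looked up, chosen after their values were seen, and no test of clustering over all called genes was made. No gene lies between Pilra and Pilrb1 in the annotation, 1 between Pilrb1 and Pilrb2, and 3 between Cd209a and Cd209d. Around Bcl6, 20 tested neighbours, 10 on each side, were examined. Lpp, which encodes a focal adhesion protein and is parted from Bcl6 by 9 genes, rose in cKO cDC1 (2.32 ± 0.31, adjusted p = 5.65e-05), and the other 19 were not called there. In cDC2 none of the 20 passed in limma's test (Lpp 1.11 ± 0.29, adjusted p = 0.0604), with values from −0.44 in Hes1 to 1.11, and in pDC none did either, with values from −0.68 in Rfc4 to 0.94 in Rtp4.

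In cKO cDC1, 36 called genes reached a mean above that of each of the other 5 groups.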
